A study of Mus musculus with 4 samples.

How the data were processed

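Messenger RNA was sequenced from MLE-12 cells, an immortalised mouse alveolar epithelial line, that were labelled either wild type or Lingo1 knockout. Each genotype was sampled unscratched and 24 hours after a scratch wound, with 1 library per condition and 4 libraries in all. Per the labels' protocols, RNA was isolated with a column kit and made into libraries with a strand-specific kit for mRNA. The wild-type unscratched, wild-type scratched, knockout-labelled unscratched and knockout-labelled scratched libraries held 26903429, 27907279, 29533746 and 48333801 counts.

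The authors deposited a table of raw read counts for 46078 Ensembl genes and a table of RPKM values (reads scaled to gene length and library size) for 14844 of those genes, 161 of them without values. Trimmomatic 0.39, STAR 2.7.9a, HTSeq 0.11.3, edgeR 3.32.1 and the mouse build mm10 are named per the submitters' processing notes, without the role of each. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap another gene or an antisense partner are uncertain. No gene of the RPKM table had under 12 reads over the 4 libraries, so the authors' RPKM values had been filtered on low counts. The library factors behind the RPKM values differed from the ratios of total counts by -0.22%, -0.19% and -0.75%, which points to a scaling beyond totals. All main values came from the counts, and the RPKM values served as an alternative with a pseudocount of 0.1. Table columns were matched to libraries by genotype and by the letter for the scratched cells, and the remaining letter was read as unscratched because no other condition was labelled. Every statement on the scratch rests on that reading. A GENCODE annotation of the same build gave positions and types. Names came from the authors' RPKM values or, for genes without a name there, from a reference list of gene names. Of the 46078 identifiers, 45143 matched that reference list.

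Counts were scaled with TMM factors, which lay between 0.991 and 1.007, and genes with at least 1 CPM (counts scaled to a fixed library total) in at least 1 library were tested: 12348 genes, 11610 of them protein-coding. With 1 library per condition no difference has a replicate check and no p-value was computed for a condition. The fold of a gene between libraries is the ratio of its CPM, with an exact 95% Clopper-Pearson interval on the split of the counts. A gene was called at least 2-fold higher or lower when its log2 difference in CPM, with a prior count of 2, was at least 1 in size and its interval excluded 1. The difference of the scratch responses had to be at least 1 in size on the log2 scale and beyond its 95% counting interval. Intervals cover counting error only, since 1 library per condition shows no variation between cultures or library preparations. The reads carry no molecular identifiers, so duplicate reads could not be set apart and the intervals may be too narrow. A floor of 3 counts corresponds to 0.111, 0.108, 0.101 and 0.0626 CPM in the wild-type unscratched, wild-type scratched, knockout-labelled unscratched and knockout-labelled scratched libraries.

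As a secondary analysis, an additive model of genotype and scratch was fitted to all 4 libraries with edgeR's quasi-likelihood F-test and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. It leaves 1 residual degree of freedom, and its spread (5.49% biological coefficient of variation, 25.4 prior degrees of freedom) comes from how far the scratch response differs between the genotypes. Its p-values therefore compare these libraries and carry no replicate cultures. "Rose" and "fell" are used only for genes that passed this test, and for groups the number that passed is given, followed by the number when p-values were adjusted over the list alone. All folds and tests were computed with R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures with matplotlib 3.10.9.

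The design, the 37 gene lists, the fold rule and the rule for naming genes were fixed before the data were examined. Of these lists, 1 is not reported here, and the others cover the LINGO and Nogo receptor group, the EGFR family, integrin adhesion, epithelial junctions, mesenchymal genes, markers of alveolar type 1, alveolar type 2, Krt8-positive transitional, airway, fibroblast, endothelial, leukocyte and neuronal cells, matrix and proteases, TGF-beta, YAP targets, immediate early genes, S phase, G2 and M phase, p53, interferon, NF-kB and cytokines, cholesterol, fatty acid synthesis, glycolysis and hypoxia, nuclear and mitochondrial respiratory chain genes, the unfolded protein response, ATF4 and amino acids, NRF2, heat shock, Wnt and Notch, axon guidance, replication-dependent histones, ribosomal proteins and housekeeping genes. For each list the median log2 difference of its tested members was placed among 10000 random lists of the same size matched on mean expression in 20 bins, over 148 list and comparison pairs. Named genes are Lingo1, the up to 12 highest and 12 lowest genes shared by both knockout comparisons and by both scratch comparisons, the up to 8 highest and 8 lowest in the difference of scratch responses, all with at least 5 CPM in a library, and the up to 4 members of a list with the largest difference. Numbered gene models were counted without being named.

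The fold rule was tested on counts simulated with counting error only for the unscratched knockout comparison over 12348 genes. It called 2.0% of genes changed 1.5-fold, 94.0% at 2.5-fold and 100.0% at 3-fold, and 7 of 12019 unchanged genes. The additive test on a simulated knockout effect over 12240 genes recovered 42.9% at 1.25-fold, 89.8% at 1.5-fold and 98.0% at 2-fold, and called 9 of 12043 unchanged genes. That simulation gave all genes 1 common dispersion of 0.00301 and no scratch response that differs between genotypes. Neither simulation holds replicate cultures, so these numbers are not error rates of the 4 libraries. Alternatives covered the scaling, prior count, expression filter, fold minimum, counting interval, RPKM values, DESeq2 and limma-voom. Removal of a trend with GC content and length, removal of chromosome medians, a restriction to protein-coding genes and thinning to equal totals were added after seeing the data. GC content was known for 99.7% of tested genes.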

Results

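The series profiled the role of Lingo1, a leucine-rich repeat membrane protein known from Nogo receptor signalling in neurons, in the repair of a lung epithelial monolayer. The 4 libraries form a design of genotype by scratch wound. Reads were found for 19005 genes in wild-type unscratched, 18794 in wild-type scratched, 19347 in knockout-labelled unscratched and 20455 in knockout-labelled scratched cells. The last library was the deepest, so its low counts are the most precise. No condition had a replicate.

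Lingo1 mRNA was not lower by 2-fold in either library labelled knockout. The gene (ENSMUSG00000049556, chromosome 9, 56618475 to 56796468, minus strand, mm10) was counted at 46.4 CPM in wild-type unscratched and 42.9 CPM in wild-type scratched cells, against 41.2 and 41.4 CPM in the knockout-labelled unscratched and scratched cells. The knockout to wild-type ratio was 0.889 (95% interval 0.821 to 0.963) without a scratch and 0.966 (0.899 to 1.04) after it, from 1196 to 1984 counts per library. After the scratch, Lingo1 stood at 0.924 times its unscratched level in wild-type cells (0.853 to 1.00) and at 1.01 times in the knockout-labelled cells (0.935 to 1.08). A gene edit that leaves the transcript in place would not show in these counts, so genotypes are given here as labelled.

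Biglycan, a type I collagen chain, airway mucins and surfactant protein B were far higher in both libraries labelled knockout than in wild type. Biglycan (Bgn, chromosome X, 73483602 to 73495933), a small matrix proteoglycan, was 74.4-fold higher without a scratch (95% interval 37.6 to 173) and 67.7-fold higher after it (34.2 to 157), from 0.295 and 0.287 CPM in wild type to 22.0 and 19.4 CPM. Col1a1 (chromosome 11, 94936224 to 94953042), the alpha-1 chain of type I collagen, was 9.26-fold (8.50 to 10.1) and 10.7-fold (9.75 to 11.8) higher, reaching 197 and 177 CPM. The gel-forming airway mucin Muc5b (chromosome 7, 141839070 to 141873084) was 7.57-fold and 6.06-fold higher, and its neighbour Muc5ac 5.17-fold and 4.59-fold. Surfactant protein B (Sftpb, chromosome 6, 72304610 to 72314371), a product of alveolar type 2 cells, was 4.19-fold (3.86 to 4.56) and 4.09-fold (3.76 to 4.45) higher.

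Other genes with large higher levels had varied roles. Mcpt1 (chromosome 14, 56017971 to 56020384), a mast cell protease gene with close paralogs that make its count uncertain, was 14.1-fold and 16.5-fold higher in the knockout-labelled unscratched and scratched libraries. Dysf, a membrane repair protein, was 10.9-fold and 9.36-fold higher, As3mt, an arsenic methyltransferase, 5.94-fold and 7.76-fold, and the transcription factor gene Gata5 4.94-fold and 4.83-fold. Plcb1, a phospholipase C, stood 4.30-fold and 4.11-fold higher, the NAD synthesis gene Nmnat2 4.92-fold and 4.05-fold, and Emilin1, a glycoprotein of elastic fibres, 4.10-fold and 5.08-fold. Dysf, As3mt, Gata5, Muc5ac and Emilin1 stayed below 10 CPM in every library, so their folds carry wide intervals, such as 6.16 to 20.8 for Dysf without a scratch.

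**Figure D1:**
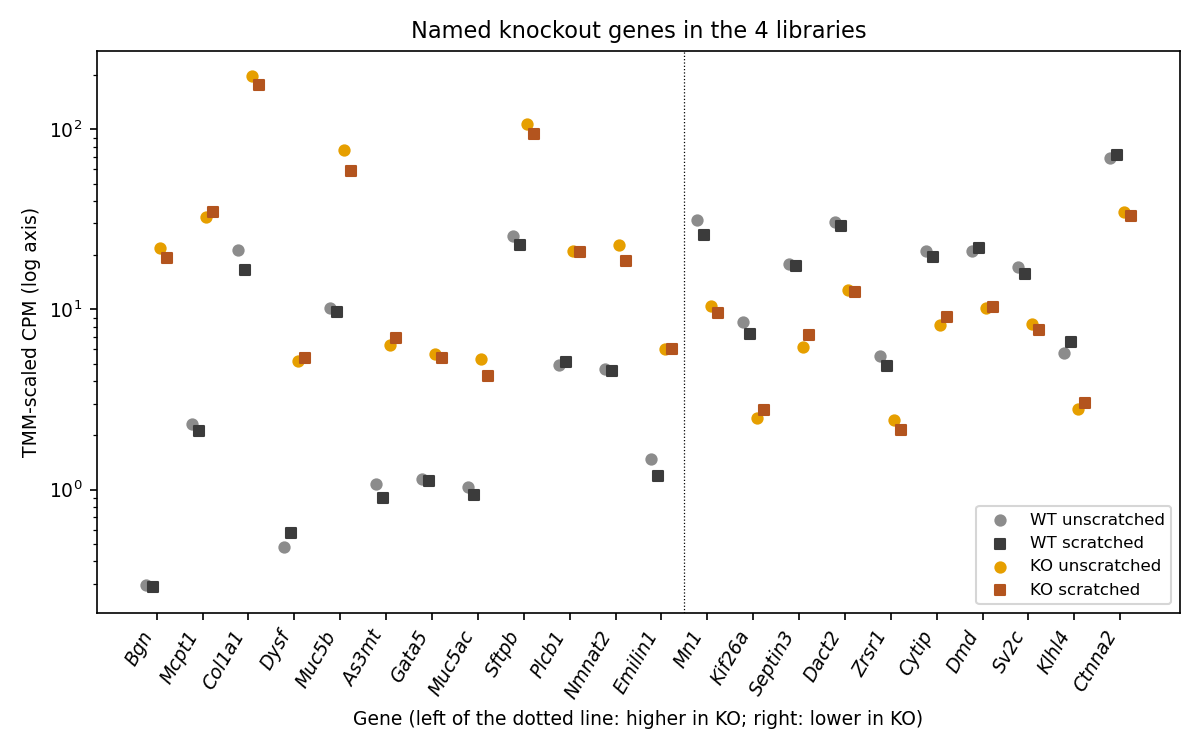
TMM-scaled CPM on a log axis of the 22 genes named for the knockout differences, with circles for unscratched and squares for scratched libraries, grey for wild type and orange for knockout-labelled cells, 1 library per point. Within each genotype the unscratched and scratched points lie close together, as for Sftpb at 25.4 and 22.9 CPM in wild type and 107 and 93.5 CPM in the knockout-labelled libraries.

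The genes lower in both knockout-labelled libraries differed by smaller folds. Mn1 (chromosome 5, 111417362 to 111457033), a transcriptional regulator, was 3.02-fold lower without a scratch (2.65 to 3.45) and 2.71-fold lower after it (2.41 to 3.06), and the kinesin family gene Kif26a was 3.41-fold and 2.67-fold lower. Septin3 was 2.88-fold and 2.43-fold lower, Dact2, a modulator of Wnt signalling, 2.40-fold and 2.33-fold, and Cytip, a cytohesin-binding protein, 2.58-fold and 2.16-fold. Zrsr1, a splicing factor gene with a close paralog, was 2.26-fold and 2.25-fold lower, and dystrophin (Dmd) 2.07-fold and 2.13-fold. The synaptic vesicle gene Sv2c (2.08-fold and 2.06-fold), Klhl4 (2.04-fold and 2.19-fold) and the catenin gene Ctnna2 (2.01-fold and 2.18-fold) lay near the 2-fold minimum. Only these 10 lower genes met the naming rule.

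Without a scratch, 277 of the 12348 tested genes were at least 2-fold different in the library labelled knockout, 168 higher and 109 lower. After the scratch, 234 were, 181 higher and 53 lower. In counts simulated with counting error only, 12 and 6 genes passed the same rule. The 2 knockout comparisons share no library, and 139 genes passed in both and in the same direction, while 22 went in opposite directions. Of the 139, 80.6% were higher, against 2.46 genes for independent lists, and 27 were lower, against 0.468. Across genes, which are not independent replicates, the 2 knockout differences correlated with a Pearson coefficient of 0.63 and a Spearman coefficient of 0.62. The same sign was seen for 72.8%. In the additive fit, 3205 genes passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, 1704 higher and 1501 lower, with a median fold of 1.22. DESeq2 called 941, of which 940 were among the 3205.

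**Figure D2:**
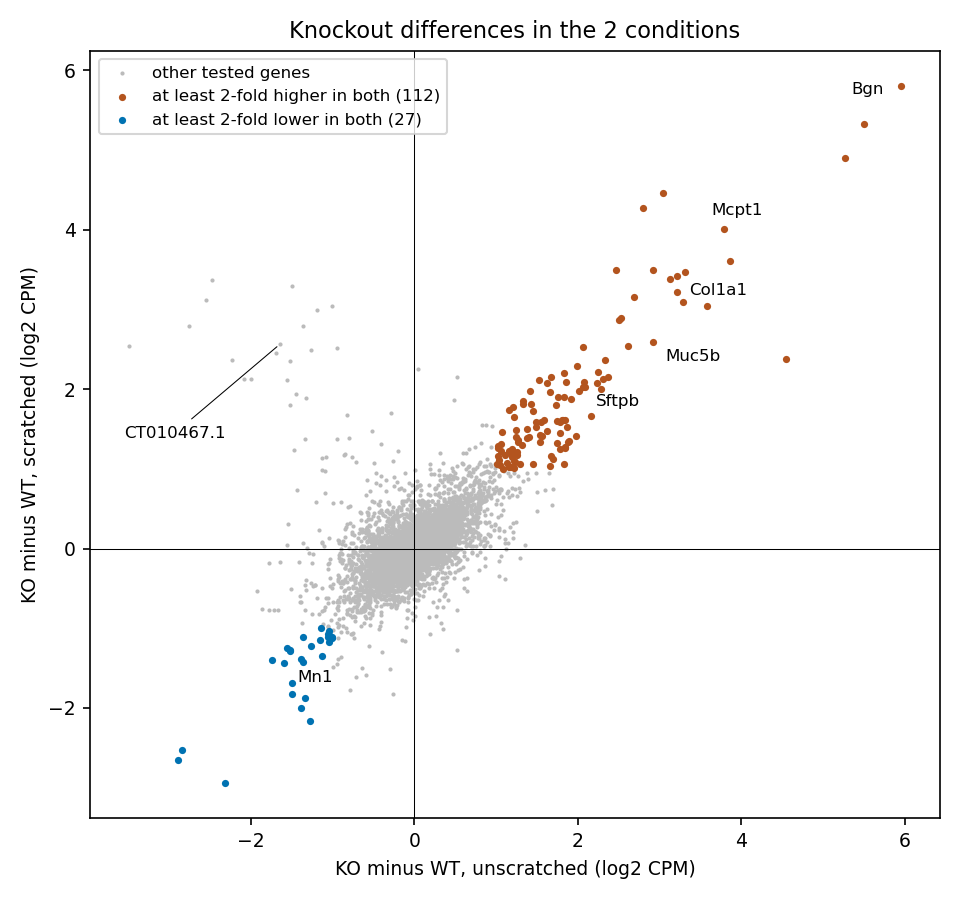
Log2 CPM difference between the knockout-labelled and wild-type libraries for each of the 12348 tested genes, unscratched on the horizontal and scratched on the vertical axis. The genes higher in both (orange) include Bgn, Mcpt1, Col1a1, Muc5b and Sftpb, the 27 lower in both (blue) include Mn1, and CT010467.1, a ribosomal RNA locus, lies among the genes that go in opposite directions.

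Cell type and cell state lists differed between the genotypes. Of the 29 tested mesenchymal genes, 13 rose and 5 fell in the libraries labelled knockout by edgeR's quasi-likelihood test (13 and 5 adjusted over the list alone), led by Bgn, Col1a1, the calcium-binding protein S100a4 (log2 1.63 ± 0.14 SE) and the collagen chain Col6a1 (0.99 ± 0.06). Of 15 alveolar type 2 genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone): Sftpb, surfactant protein C (Sftpc, 1.74 ± 0.10) and the protease Ctsh that processes it (0.74 ± 0.06) rose, and the lung transcription factor Foxa1 fell (-0.44 ± 0.06). Of 7 tested airway genes, 4 rose and 0 fell (5 and 0 adjusted over the list alone): Muc5b, Muc5ac and the basal keratin Krt14 (0.73 ± 0.05) rose, while Aldh1a1 was at 0.04 ± 0.06. The full lists held 41 mesenchymal, 27 alveolar type 2 and 21 airway genes. Members that were not tested stayed under 1 CPM in every library, among them most of the airway list. The list medians were 0.39 and 0.33 for the mesenchymal, 0.34 and 0.28 for the alveolar type 2 and 0.68 and 0.78 for the airway genes, without and after a scratch, each at percentile 99.98 or higher among random lists. With genes of at least 5 CPM alone, the medians were 0.18 and 0.08, 0.21 and 0.18, and 1.49 and 1.46. The airway values rest on few genes, among them the neighbours Muc5b and Muc5ac.

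Markers of other cell types moved in both directions. Of 8 fibroblast genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone). Beside the rise of Col1a1 stood falls of Gucy1a1 (-0.69 ± 0.10) and of the matrix protein Npnt (-0.52 ± 0.06). Decorin (Dcn) was at 2710 CPM without and 2481 CPM after a scratch in knockout-labelled cells and 2846 and 2819 CPM in wild type. The fibroblast median of 0.86 without a scratch turned to -0.24 among genes of at least 5 CPM. After the scratch the median was 0.36 over all 8 tested genes, 5 above and 3 below 0. That value also includes genes under 5 CPM, so it is no firmer than the 0.86. Of 24 alveolar type 1 genes, 6 rose and 4 fell (6 and 4 adjusted over the list alone), with the semaphorin Sema3e (-1.02 ± 0.06) and agrin (Agrn, -0.44 ± 0.06) lower. Of 28 genes of the Krt8-positive transitional state seen in alveolar repair, 10 rose and 2 fell (10 and 3 adjusted over the list alone), among them Tnip3 (0.77 ± 0.09), Myc (0.71 ± 0.07) and the cell cycle inhibitor Cdkn1a (0.66 ± 0.12). Of 8 neuronal genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with Map2 at -0.74 ± 0.06. Of 4 endothelial genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone), and none of 3 leukocyte genes passed with either adjustment by edgeR's quasi-likelihood test. These numbers count tested genes. The full lists held 20 fibroblast, 27 alveolar type 1, 32 transitional, 25 neuronal, 18 endothelial and 22 leukocyte genes, and the rest stayed under 1 CPM.

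Glycolytic, hypoxia and ribosomal protein genes rose together in the knockout-labelled libraries. Of 36 glycolysis and hypoxia genes, 20 rose and 0 fell by edgeR's quasi-likelihood test (21 and 0 adjusted over the list alone), including hexokinase 2 (Hk2, 1.38 ± 0.14, Benjamini-Hochberg adjusted p = 1.33e-08), the phosphofructokinase Pfkl (0.84 ± 0.05), the oxygen-sensing hydroxylase Egln3 (0.72 ± 0.12) and the aldolase Aldoa (0.67 ± 0.06). Of 55 ribosomal protein genes, 49 rose and 0 fell (51 and 0 adjusted over the list alone), with Rpl3 (0.50 ± 0.06), Rps24 (0.48 ± 0.07) and Rpl6 (0.46 ± 0.06) in front. These families have many processed copies, so single members are uncertain. The medians were 0.29 and 0.19 for glycolysis and 0.35 and 0.22 for ribosomal proteins, above all 10000 random lists. Of 24 fatty acid genes, 8 rose and 2 fell (11 and 2 adjusted over the list alone), with the elongase Elovl6 (0.62 ± 0.06) and the desaturase Scd1 (0.42 ± 0.07) higher. Of 24 cholesterol genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone). Of 43 nuclear genes of the respiratory chain, 6 rose and 0 fell (2 and 0 adjusted over the list alone), among them Sdha (0.30 ± 0.06). The medians of these last 2 lists, cholesterol at 0.17 and the respiratory chain at 0.11 without a scratch (0.05 after removal of a GC and length trend), were near 0 after it, at -0.00 and 0.01, the latter of which turned negative with total counts. The unscratched comparison shares its wild-type library with the wild-type scratch response, in which both lists were also higher. So were glycolysis and ribosomal protein genes, at wild-type scratch medians of 0.12 and 0.13. A deviation of that 1 library could therefore add to the unscratched values of all 4 lists. The medians after the scratch, 0.19 for glycolysis and 0.22 for ribosomal proteins, do not use that library.

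Cell cycle genes divided by phase. Of 54 genes of G2 and M phase, 23 rose and 0 fell in the knockout-labelled libraries by edgeR's quasi-likelihood test (25 and 0 adjusted over the list alone), including Ube2c (0.50 ± 0.06), the centromere protein Cenpf (0.46 ± 0.07) and the mitotic kinase Aurka (0.43 ± 0.06). Of 46 S phase genes, 2 rose and 21 fell (2 and 28 adjusted over the list alone): the chromatin assembly factor Chaf1b fell (-0.33 ± 0.06), as did the clamp loader subunit Rfc4 (-0.25 ± 0.06), and cyclin E1 (Ccne1) rose (0.44 ± 0.11). The medians without and after a scratch were 0.18 and 0.07 for G2 and M phase and -0.13 and -0.17 for S phase, the latter below all 10000 random lists. The G2 and M phase median was also 0.09 in the wild-type scratch response, which shares the unscratched wild-type library. A deviation of that library could add to the 0.18. Of 26 p53 targets, 5 rose and 7 fell (5 and 7 adjusted over the list alone), with Cdkn1a and Plk2 (0.52 ± 0.06) higher and the pro-apoptotic Pmaip1 lower (-0.42 ± 0.11).

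Adhesion, matrix and signalling genes changed in both directions. Of 29 integrin adhesion genes, 11 rose and 2 fell in the knockout-labelled libraries (11 and 3 adjusted over the list alone), led by the integrin chains Itga9 (0.98 ± 0.15) and Itga6 (0.88 ± 0.10), talin 2 (Tln2, 0.88 ± 0.08) and the hyaluronan receptor Cd44 (0.61 ± 0.05). Of 29 matrix and protease genes, 12 rose and 5 fell (13 and 5 adjusted over the list alone), with the laminin chains Lamb1 (0.71 ± 0.06) and Lamb3 (0.65 ± 0.10) higher and the plasminogen activator Plat lower (-0.51 ± 0.06). Of 28 junction genes, 3 rose and 8 fell (3 and 9 adjusted over the list alone): the tight junction proteins Marveld3 (-0.62 ± 0.11) and Marveld2 (-0.36 ± 0.10) fell, and Cgnl1 (0.55 ± 0.05) and the desmosomal Pkp1 (0.47 ± 0.11) rose. Of 27 YAP targets, 10 rose and 4 fell (10 and 4 adjusted over the list alone), with the receptor kinase Axl at 0.69 ± 0.06 and Igfbp3 at -1.02 ± 0.10. Of 26 TGF-beta genes, 8 rose and 4 fell (8 and 4 adjusted over the list alone), with the activin chain Inhba higher (0.68 ± 0.08) and the co-receptor Tgfbr3 lower (-0.61 ± 0.08).

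In the groups tied to Lingo1 and to neuronal guidance, genes passed in both directions. Of 10 LINGO and Nogo receptor genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone): the multiligand receptors Lrp1 (0.51 ± 0.06) and Sort1 (0.28 ± 0.06) rose, and Lingo1 itself was at -0.11 ± 0.06 (adjusted p = 0.216, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of 16 EGFR family genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), the ligand Hbegf and the feedback inhibitor Errfi1 rising by 0.20 ± 0.07 and 0.26 ± 0.09. Of 40 axon guidance genes, 10 rose and 13 fell (10 and 15 adjusted over the list alone), with Sema4a (1.55 ± 0.14) higher and Sema3e and Sema3d (-0.90 ± 0.06) lower. Of 28 Wnt and Notch genes, 10 rose and 4 fell (11 and 4 adjusted over the list alone), with the secreted Wnt binder Sfrp2 (1.10 ± 0.13) and the Notch ligand Jag1 (0.47 ± 0.08) higher.

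More interferon-stimulated genes fell than rose in the libraries labelled knockout. Of 40 such genes, 1 rose and 12 fell by edgeR's quasi-likelihood test (1 and 17 adjusted over the list alone), among them Oasl1 (-0.60 ± 0.12), the guanylate-binding protein Gbp2 (-0.50 ± 0.10) and the ubiquitin-like Isg15 (-0.42 ± 0.12). The list medians were -0.07 without and -0.19 after a scratch, the latter -0.13 among genes of at least 5 CPM. Of 24 NF-kB and cytokine genes, 6 rose and 4 fell (6 and 4 adjusted over the list alone), with Il18 (0.82 ± 0.15) and Mif (0.70 ± 0.07) higher. Of 33 immediate early genes, 7 rose and 14 fell (9 and 15 adjusted over the list alone): the ERK phosphatase Dusp4 rose (1.91 ± 0.12), while Jun (-0.59 ± 0.07) and Fosb (-0.50 ± 0.12) fell. The list median was -0.17 without a scratch but 0.01 after it. For Fosb the knockout to wild-type ratio was 0.576 (0.495 to 0.669) without a scratch and 0.894 (0.750 to 1.07) after it. Of 29 unfolded protein response genes, 10 rose and 6 fell (10 and 6 adjusted over the list alone), with Xbp1 higher (0.78 ± 0.09) and the chaperone Dnajb9 lower (-0.49 ± 0.09). Of 29 NRF2 targets, 9 rose and 8 fell (10 and 8 adjusted over the list alone), of 27 ATF4 and amino acid genes 4 and 4 (4 and 4 adjusted over the list alone), and of 23 heat shock genes 2 and 2 (2 and 2 adjusted over the list alone). Of 17 housekeeping genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), Pgk1, Eef1a1 and Gapdh by 0.47 ± 0.05, 0.42 ± 0.07 and 0.39 ± 0.06.

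**Figure D3:**
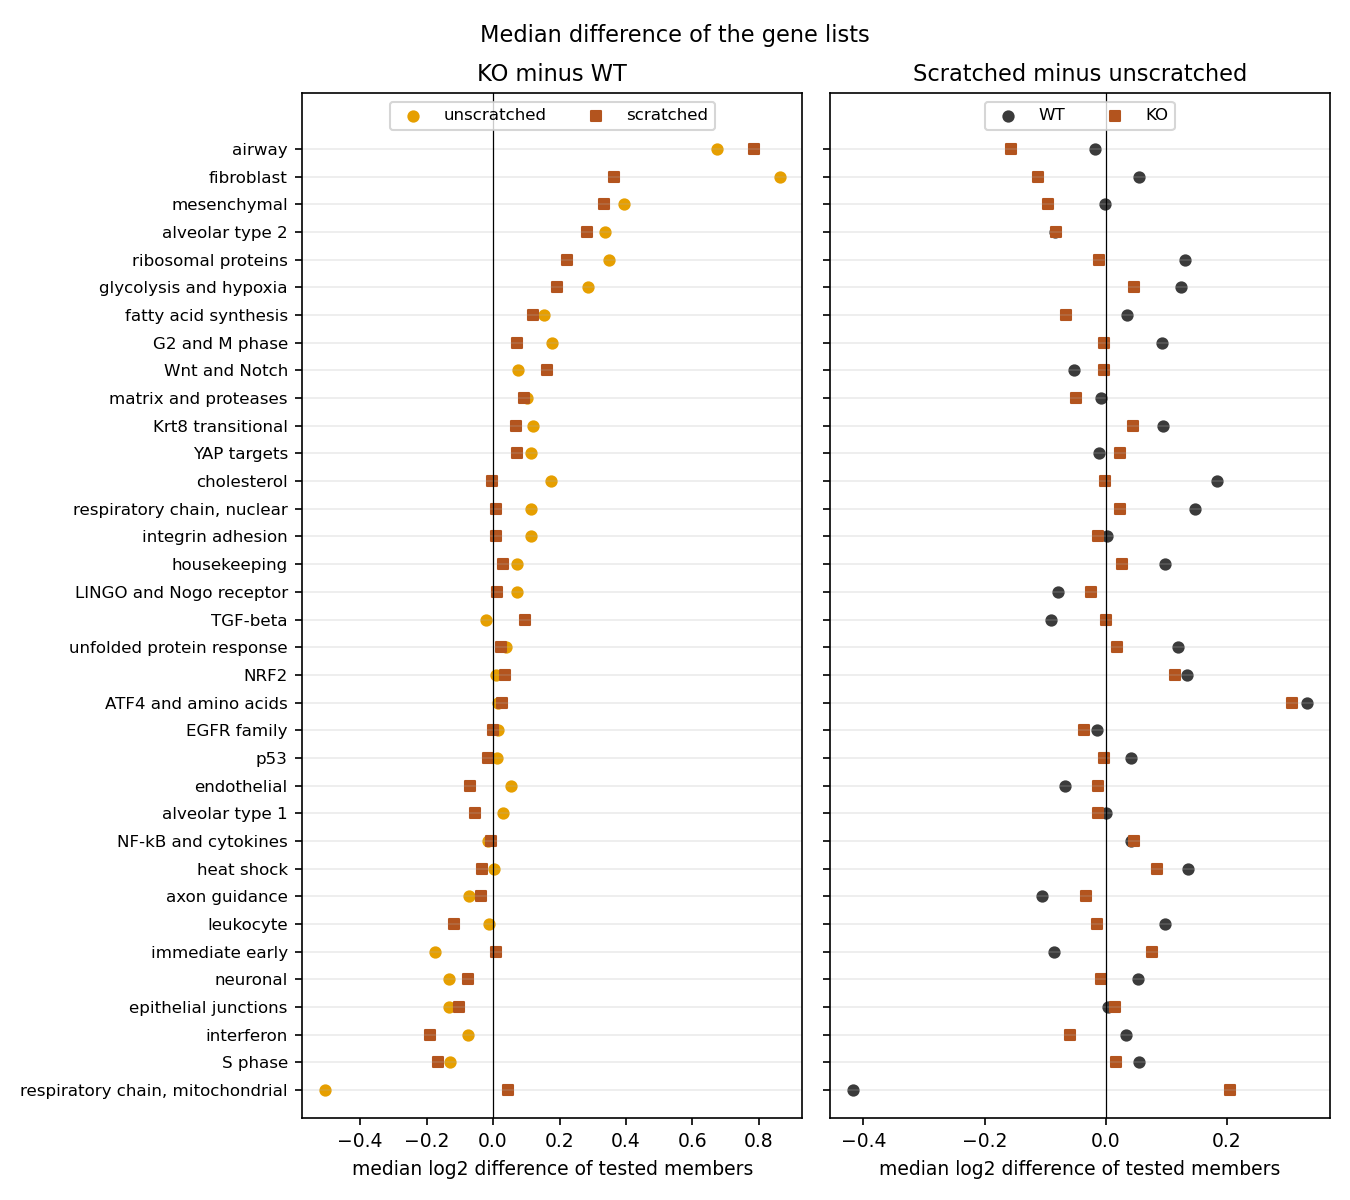
Median log2 CPM difference of the tested members of the gene lists, knockout-labelled minus wild type on the left and scratched minus unscratched on the right, with 1 point per comparison of 2 libraries; replication-dependent histones, with medians of up to 2.12, are left out to keep the scale. The ATF4 and amino acid list stands highest after the scratch in both genotypes, at 0.33 and 0.31, and 14 medians near 0 change sign under another scaling.

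After the scratch, genes of the amino acid response rose in both genotypes, at modest folds. ATF4 is the transcription factor that raises amino acid synthesis and uptake under amino acid or endoplasmic reticulum stress. Of the 27 tested genes of this list, 16 rose and 1 fell after the scratch by edgeR's quasi-likelihood test (22 and 2 adjusted over the list alone). The median was 0.33 in wild-type and 0.31 in knockout-labelled cells, above all 10000 random lists in both. Asparagine synthetase (Asns) rose by 0.57 ± 0.06 (Benjamini-Hochberg adjusted p = 1.82e-06), the pseudokinase Trib3 by 0.56 ± 0.08, the leucine transporter Slc7a5 by 0.53 ± 0.06, the mitochondrial folate enzyme Mthfd2 by 0.51 ± 0.06 and the serine synthesis enzyme Psph by 0.51 ± 0.07. The stress gene Nupr1 rose by 0.42 ± 0.10, from 17.1 to 26.6 CPM in wild type and from 14.0 to 16.0 CPM in knockout-labelled cells.

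**Figure D4:**
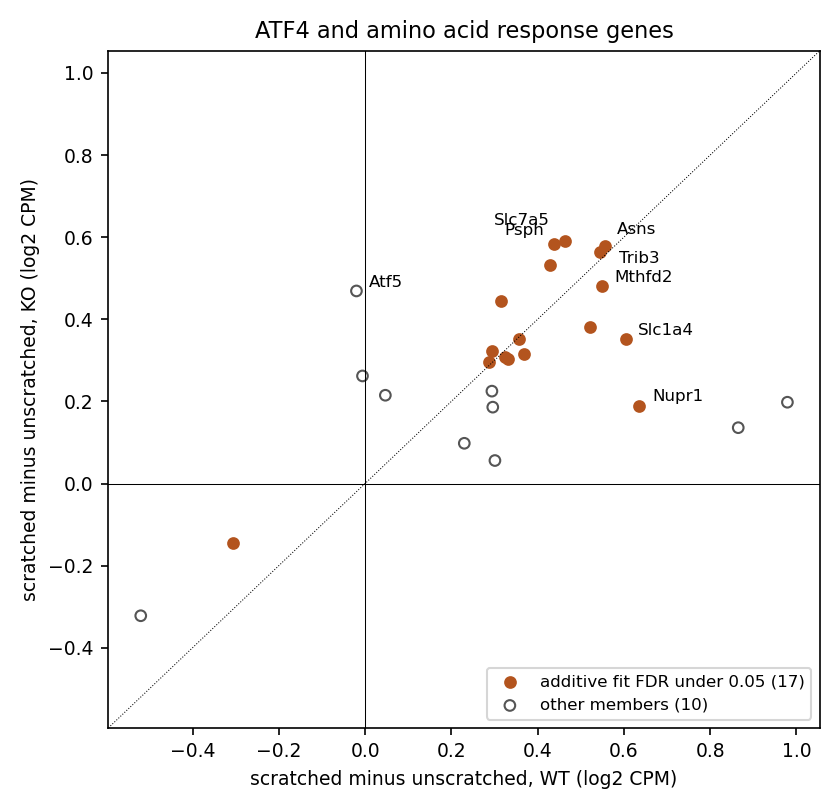
Scratched minus unscratched log2 CPM of the 27 tested ATF4 and amino acid genes in wild-type (horizontal) and knockout-labelled cells (vertical), with filled points for the 17 that passed the additive test, 16 higher and 1 lower. The dotted line marks equal responses, and Asns, Mthfd2 and Slc7a5 lie near it, above 0 on both axes.

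Fewer members of the other stress and signalling lists rose after the scratch. Of 29 NRF2 targets, 6 rose and 0 fell by edgeR's quasi-likelihood test (14 and 0 adjusted over the list alone), among them the quinone reductase Nqo1 (0.28 ± 0.05), Srxn1 (0.24 ± 0.06) and the cystine transporter Slc7a11 (0.32 ± 0.09). The median of these targets was 0.13 in wild-type and 0.11 in knockout-labelled cells. Removal of a GC and length trend lowered the wild-type median to 0.08. Of 23 heat shock genes, 3 rose and 1 fell (9 and 2 adjusted over the list alone), with the chaperonin Hspd1 higher (0.31 ± 0.06) and Hspa1b lower (-0.42 ± 0.12). Of 36 glycolysis and hypoxia genes, 2 rose and 2 fell (8 and 4 adjusted over the list alone). Hk2 rose by 0.74 ± 0.13 (adjusted p = 0.00202). Of 28 transitional genes, 3 rose and 0 fell (5 and 1 adjusted over the list alone): the cornified envelope gene Sprr1a (0.73 ± 0.09), Nupr1 and Myc (0.36 ± 0.07). Of 16 EGFR family genes, the ligand neuregulin 1 (Nrg1, 0.73 ± 0.14) rose, so 1 rose and 0 fell (2 and 1 adjusted over the list alone). Of 26 p53 targets, 4 rose and 0 fell (5 and 0 adjusted over the list alone), with Aen at 0.41 ± 0.09.

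Matrix and signalling genes showed few passing members after the scratch. Transforming growth factor beta 1 (Tgfb1) fell by 0.40 ± 0.06 on the log2 scale (Benjamini-Hochberg adjusted p = 0.000685, edgeR quasi-likelihood test), and 0 of 26 TGF-beta genes rose and 2 fell (1 and 4 adjusted over the list alone). Of 29 matrix and protease genes, 0 rose and 2 fell (2 and 3 adjusted over the list alone), the laminin chain Lama5 (-0.33 ± 0.06) and perlecan (Hspg2, -0.30 ± 0.06). Of 33 immediate early genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone): Fosb fell from 16.8 to 7.64 CPM in wild-type and from 9.67 to 6.83 CPM in knockout-labelled cells. Of 27 YAP targets, 2 rose and 0 fell (2 and 0 adjusted over the list alone), Edn1 (0.45 ± 0.08) and Ankrd1 (0.29 ± 0.06). Lrp1 fell (-0.46 ± 0.06), as the 1 LINGO and Nogo receptor gene to pass with 0 rising (0 and 1 adjusted over the list alone). Of 28 junction genes, 1 rose and 0 fell (1 and 0 adjusted over the list alone), of 29 unfolded protein response genes 2 and 0 (2 and 0) and of 24 NF-kB and cytokine genes 1 and 0 (2 and 1).

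Few members of the cell type lists passed for the scratch. By edgeR's quasi-likelihood test, 0 of 15 alveolar type 2 genes rose and 1 fell (0 and 3 adjusted over the list alone). In the airway list, 0 of 7 genes rose and 1 fell (1 and 1 adjusted over the list alone), with Muc5b at -0.30 ± 0.08. Of 8 neuronal genes, 2 rose and 0 fell (2 and 1 adjusted over the list alone), with the tubulin Tubb3 at 0.63 ± 0.09. Of 17 housekeeping genes 1 rose and 0 fell (1 and 0 adjusted over the list alone). In the mesenchymal, fibroblast, endothelial, fatty acid, integrin adhesion, alveolar type 1, leukocyte, S phase, G2 and M phase, interferon, cholesterol, nuclear respiratory chain, Wnt and Notch, axon guidance and ribosomal protein lists, 0 members passed in either direction. Adjusted over the list alone, 1 mesenchymal, 1 fibroblast and 1 endothelial gene fell, 1 fatty acid gene rose, and none passed in the others. The fit counts a response of 1 genotype as error, so a list without passing members may still differ in 1 genotype. Wild-type medians were 0.09 for G2 and M phase, 0.15 for the nuclear respiratory chain and -0.10 for axon guidance genes. In knockout-labelled cells they were -0.00, 0.02 and -0.03. The mesenchymal median was -0.00 in wild-type and -0.10 in knockout-labelled cells. Over all genes, 1998 of 12348 had an unadjusted p under 0.05 for the scratch, 359 passed edgeR's test after adjustment, DESeq2 called 41 and limma-voom 311. Ribosomal protein and cholesterol medians were 0.13 and 0.18 after the scratch in wild type and near 0 in the knockout-labelled cells, at -0.01 and -0.00. The wild-type scratch response shares its unscratched library with the unscratched knockout difference, where cholesterol stood at 0.17 and the nuclear respiratory chain at 0.11. A deviation of that 1 library would raise both values and cannot be told apart from a response. Removal of the GC and length trend lowered the wild-type ribosomal protein median to 0.07.

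By the 2-fold rule the scratch response was small. In wild-type cells 15 genes were at least 2-fold higher and 91 lower after the scratch, and in the knockout-labelled cells 21 were higher and 12 lower, against 14 and 2 genes in counts simulated with counting error only. The excess of higher genes in knockout-labelled cells turned with a fold minimum of 1.5, to 65 higher and 86 lower. It turned also without an expression filter, to 84 higher and 142 lower, and held under the other settings. Among protein-coding genes alone the wild-type numbers were 12 and 40. Genes past the rule in both genotypes numbered 4, all lower, against 0.0884 for independent lists, while 16 other genes went in opposite directions. The 4 shared genes were Nrtn, a neurotrophic factor (34 to 8 counts in wild type and 17 to 11 in knockout-labelled cells), Cpt1b, a muscle carnitine transferase, and the gene models Gm9917 and Gm43333. They were named because so few passed and after their values were seen, and none reached 5 CPM. Across genes the 2 scratch responses correlated with coefficients of 0.12 (Pearson) and 0.29 (Spearman), and 61.3% had the same sign. In the additive fit 181 genes rose and 178 fell after the scratch, with a median fold of 1.21. Chosen after their values were seen, the nuclear RNA Neat1 fell by 0.74 ± 0.07 on the log2 scale, from 259 to 138 CPM in wild-type and from 271 to 184 CPM in knockout-labelled cells, and the spermidine synthase Srm rose by 0.53 ± 0.06.

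The scratch responses of the genotypes differed most, among genes of at least 5 CPM, in ribosomal and small structural RNAs. The ribosomal RNA locus CT010467.1 (chromosome 17, 39846353 to 39848827) was 4.93-fold lower after the scratch in wild-type and 3.75-fold higher in knockout-labelled cells, a log2 difference of 4.21. The same was seen for Rpph1, the RNA of ribonuclease P (6.05-fold lower and 2.47-fold higher), and Rn7sk, an RNA that restrains transcription elongation (3.74-fold lower and 2.48-fold higher). The 5.8S ribosomal RNA gene n-R5-8s1 was 5.49-fold lower and 1.89-fold higher, and mitochondrial ribosomal RNA (mt-Rnr1) 2.63-fold lower and 1.73-fold higher. Rny3 was 21.7-fold lower in wild type (10.8 to 51.2) and at a ratio of 1.03 in knockout-labelled cells. Rpl23a and Gnas, with differences of 2.22 and 2.07, were counted at only 84 to 322 and 24 to 144 reads, and as multi-copy and overlapping genes they are uncertain. In all, 108 genes passed the rule for this difference, 84 higher in the knockout-labelled response and 24 lower, the lower ones all below 5 CPM, against 44 in counts with counting error only. With 1 library per condition the difference has no test.

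Structural RNA took 0.683% of counts in wild-type unscratched, 0.151% in wild-type scratched, 0.242% in knockout-labelled unscratched and 0.777% in knockout-labelled scratched cells. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had medians of -1.85 after the scratch in wild-type and 1.62 in knockout-labelled cells, and knockout differences of -1.31 without and 2.12 after a scratch. Of the 21 listed genes 8 were tested, and only H1f2 reached the 5 CPM needed for naming, so these medians rest on low counts. Of the 8, 2 rose in the knockout-labelled libraries and 0 fell (2 and 0 adjusted over the list alone), with H1f2 at 0.83 ± 0.11. With the scratch, none of the 8 passed edgeR's quasi-likelihood test with either adjustment. The 7 mitochondrially encoded genes had scratch medians of -0.42 and 0.21 and knockout medians of -0.51 and 0.04. In the additive fit 0 rose and 4 fell in the knockout-labelled libraries (0 and 4 adjusted over the list alone), but all 7 were lower without a scratch and slightly higher after it, as mt-Nd6 at -0.64 and 0.03, so these calls rest on the unscratched pair alone. None passed for the scratch. Immediate early genes had scratch medians of -0.09 and 0.08 and knockout medians of -0.17 and 0.01, the last of which turned negative with total counts.

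**Figure D5:**
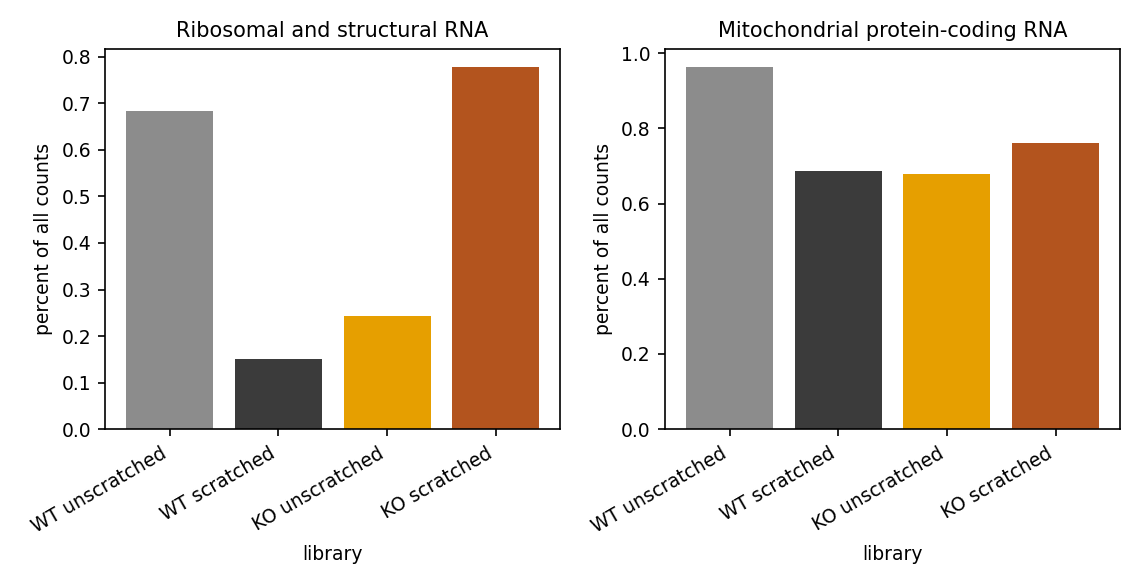
Percent of all counts taken by ribosomal and other structural RNA (left) and by mitochondrial protein-coding RNA (right) in each of the 4 libraries, with bars from 0. Structural RNA was high in wild-type unscratched (0.683%) and knockout-labelled scratched cells (0.777%) and low in the other 2 libraries, and mitochondrial RNA ran from 0.679% to 0.962%.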

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

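In this part, the tests for carry-over of structural RNA were chosen only after the result was seen. Of the genes whose scratch responses went in opposite directions in the genotypes, 4 were flagged, each with 1 library per condition, so that the difference itself was not tested. The log2 difference of the responses, knockout-labelled minus wild type, was 4.21 for the ribosomal RNA locus CT010467.1, 3.87 for Rpph1, 3.21 for Rn7sk and 2.03 for Lars2. Lars2, a mitochondrial leucyl-tRNA synthetase gene that overlaps a ribosomal RNA repeat, was counted at 2558 and 1250 CPM in wild-type unscratched and scratched cells and at 1420 and 2842 CPM in the knockout-labelled ones, so its count is uncertain.

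These genes belong to 1 pattern, the scratch responses that differ between the genotypes. After removal of a trend with GC content and length, 100% of the count of genes was left, as 89 higher and 19 lower. At equal totals, a test of the deeper sequencing of the scratched knockout-labelled library, 103.7% was left, as 88 higher and 24 lower. The values argue against either as the whole source of the number of genes. They compare numbers only, not which genes passed, so a part in single genes stays open. Of the 19 genes past the rule with at least 5 CPM in a library, 13 (68.4%) were ribosomal RNA, mitochondrial ribosomal RNA, small structural RNA or loci that overlap ribosomal RNA repeats. That share restates what prompted the test, and over all 108 genes past the rule it was 17.6% (95% interval 10.9 to 26.1%), while 64 of them were protein-coding. Unequal carry-over of RNA without a poly(A) tail in library preparation stays open for the structural RNAs, as does a genotype effect on the wound response, which was not tested.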

How the results depend on the processing

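Restriction to protein-coding genes and removal of a GC and length trend or of chromosome medians were chosen only after the result was seen, as was thinning to equal totals. No paired analysis was possible because each condition had 1 library and the labels give no replicate numbers, apart from the additive fit, which combines the knockout comparisons across the scratch; no replicate could be left out. Values below follow the order scratch in wild type, scratch in knockout-labelled cells, knockout without a scratch, knockout after a scratch, shared knockout, shared scratch and difference of scratch responses, with main counts of 106, 33, 277, 234, 139, 4 and 108 genes.

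Without an expression filter 263, 226, 611, 535, 11 (shared scratch) and 248 (difference) genes passed, because more genes were tested. With at least 5 CPM, which tests fewer genes, 21, 6, 86, 85, 58, 0 and 19 passed. A fold minimum of 1.5 gave 294, 151, 793, 648, 386, 22 and 240 and a minimum of 3 gave 37, 9, 88, 97, 52, 1 and 44, by construction. The authors' RPKM values gave 70 and 15 for the scratch responses, 155 for the knockout after a scratch and 2 for the shared scratch; the cause was not tested. A prior count of 5 gave 18 for the scratch in knockout-labelled cells and 1 for the shared scratch, by its shrinkage of low counts. Among protein-coding genes, a smaller set, 52, 20, 2 (shared scratch) and 64 (difference) passed. In the additive fit DESeq2 called 941 genes for the knockout and 41 for the scratch, against 3205 and 359, and protein-coding genes alone gave 600 for the scratch; the cause was not tested.

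The alternatives were compared for the list medians beyond the outer 0.5% of random lists. Of these values, 316 stayed within the limits of the main value, 15 moved and 1 reversed. The reversed value was that of the fibroblast list in the unscratched knockout comparison. It fell from 0.86 to -0.24 with genes of at least 5 CPM, where fewer genes were tested. Among the remaining list medians, 14 of at most 0.0242 in size changed sign under another scaling. Removal of the GC and length trend moved the wild-type scratch medians of G2 and M phase genes to 0.05, of the nuclear respiratory chain to 0.06 and of ribosomal proteins to 0.07. For named genes 418 values stayed and 10 moved. The number of list medians beyond the outer 0.5% of random lists was 48 and ran from 42 to 50, and that of named knockout genes past the rule was 22 and ran from 19 to 22. Removal of the median of each chromosome kept all counts within 1.5 times. RLE, total count and upper quartile scaling did so too and moved the median of all genes by at most 0.03. Depth limits genes of low count, whose counting intervals are wide.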

Other observations

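The tests of the rise of fibroblast genes over wild type, of chromosome medians, of carry-over in the amino acid genes and of chromosome 4 were chosen only after the result was seen. Protein-coding genes on chromosome 4 were slightly lower in both libraries labelled knockout. The median log2 difference of its 755 tested protein-coding genes was -0.16 without and -0.16 after a scratch, 73.5% of them were lower in both, and the largest median in size on another chromosome was -0.08, on chromosome 16 after a scratch. All 12 windows of 10 Mb on chromosome 4 with at least 20 tested protein-coding genes had medians below 0 in both comparisons, between -0.10 and -0.23, against 44 of 196 such windows (22.4%) elsewhere. None of the other 196 windows was as low in both comparisons as the highest window of chromosome 4, but 4 were as far above 0, all in the distal part of chromosome 2, with medians of up to 0.19 and 0.21. Of the 139 genes at least 2-fold different in both comparisons, 10 lay on chromosome 4, only 2 of them lower, and none of the 22 named genes did.

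The 100% of chromosome 4 windows of at least 20 genes below 0 largely restates the shift and does not test its source. Fewer copies of chromosome 4 in the knockout line, in part of its cells, and a shared regulatory change stay open, and DNA copy number was not analysed here.

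Knockout differences shared by both conditions covered 139 genes. Removal of a GC and length trend left 96.4% of them by count, which argues against that trend as the whole source. Removal of the median of each chromosome left 99.3%. The largest such median was -0.16, so its removal could take out only genes near the 2-fold limit. Shifts of whole chromosomes by that size are too small to make 2-fold differences, but copy number of single segments was not tested. The share on chromosomes shifted by at least 0.2, 0.0%, decides nothing, because no chromosome met that limit. Fibroblasts mixed into the cultures would bring Col1a2 and Col3a1 with Col1a1, yet these stayed at or below 0.0338 and 0.203 CPM; a bound set on absolute levels gave 1376.99% of Col1a1, because Dcn is abundant in wild-type MLE-12 cells too (2846 CPM), so that bound was wrong, and the largest rise over wild type was 0.57% of the rise of Col1a1, for Pdgfra. A lasting difference between the lines, from the edit or from the growth of separate clones, is a candidate explanation, and the libraries hold no second clone to part them. Lingo1 mRNA was not lower by 2-fold, so a tie to the loss of Lingo1 was not tested.

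Amino acid response genes were higher after the scratch in both genotypes. The tables argue against a GC and length trend, since 98.3% of the smaller median was left after its removal. Carry-over of structural RNA was predicted to turn the list's direction between the genotypes, and the smaller of the 2 medians was 0.307. The list was taken up because it was higher in both genotypes, so this value restates the choice and does not decide on carry-over. A response of the cells to the wound, or to nutrients of the medium after 24 hours, may underlie the higher levels, and the libraries do not part these.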
